A study of Homo sapiens with 12 samples.

How the data were processed

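Total RNA of cultured human keratinocytes was extracted with a QIAGEN RNeasy kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. There were 12 arrays in 4 groups of 3. The groups received medium (control), IL36G at 100 ng/ml, IL17A at 200 ng/ml, or both cytokines at these doses. Each array's group and replicate number were taken from its title. The replicate numbers run on from group to group, so they pair no arrays. Donors, the time of stimulation, batches and scan dates are not given in the sources used here. Nothing states that the 3 arrays of a group came from separate cultures or donors, so the p-values measure only the spread between these arrays, which may be technical.

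The values were deposited by the authors as 1 table of log2 expression values, made with GCRMA per the submitters' processing notes. GCRMA subtracts a background estimated from the sequence of each probe, normalizes by quantiles and summarises the probes of a probe set on the log2 scale. The version of GCRMA is not given in the sources used here. Values ran from 2.61 to 14.67, and the arrays' medians lay between 6.75 and 6.80, so the values were used as deposited and not normalized again. Each value column was matched to its sample by the sample identifier that names the column. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.064, and 0.090 for the interaction described below.

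Gene symbols came from the platform annotation held by GEO, matched by gene ID to RefSeq on GRCh38.p14, which served for names only. No genome build is stated with the array values, so no coordinates are given. Of 54675 probe sets, 41009 had 1 gene symbol, 1801 had several, 11721 had no symbol in the annotation used here and 62 were Affymetrix controls. The other 82 belonged to XIST, TSIX and Y-linked genes and were left out of all work because the samples are human. Probe sets with several symbols or with no symbol were left out of the gene tests and counted separately. Each gene was represented by its single-symbol probe set with the highest mean over the 12 arrays. This gave 19729 genes, of which 10505 had more than 1 probe set. A gene was tested if it lay above the array's median over all probe sets on at least 3 of the 12 arrays. This left 12463 genes and removed 7266. Another probe set of the same gene was called in the opposite direction for 71 of the 2566 genes with several probe sets that were called between the combination and control, and for at most 12 genes in each other comparison. The genes named below had no such probe set.

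All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with a mean per group and no covariate. The shared fit had 8 residual and 3.52 prior degrees of freedom. Contrasts were each cytokine condition against control, the combination against each single cytokine, IL36G against IL17A, and the interaction. The interaction is the combination effect minus the sum of the single effects on the log2 scale, and a moderated F test asked for any difference among the 4 groups. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all tested genes. Values are log2 fold changes ± standard error (SE) from this fit unless a group mean ± SD is named, and n is 3 arrays per group. Genes higher in the combination than with each single cytokine were also tested against the linear sum, which adds the increments of the single cytokines over control on the unlogged scale. The standard error of that difference came from the delta method with limma's moderated variances, and p was adjusted over these genes.

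Gene lists numbering 25 were fixed before the data were examined, as were the groups, contrasts, filter, named-gene rule and alternatives. They covered chemokines, antimicrobial proteins, cytokines and receptors, NF-kB targets, interferon-stimulated genes, keratinocyte differentiation, the SPRR family, keratins, basal genes, genes of psoriasis plaque keratinocytes and proteases. They also covered proliferation, cholesterol synthesis, glycolysis and hypoxia, 3 kinds of stress response, housekeeping genes, and markers of melanocytes, fibroblasts, leukocytes and endothelial cells. The symbols DDX58 and VNN3 in the lists were read as RIGI and VNN3P. Lists with at least 3 tested members (21 lists) were tested in the 7 contrasts with limma's camera at a preset correlation between genes of 0.01, and p was adjusted over the 147 tests. Camera called 85 tests, of which 60 held with a correlation estimated from the data. The camera p values below use the preset correlation unless an estimated one is named, so their size depends on that setting. The fry test, which asks whether the members move one way on balance without comparing them with other genes, called 108, and its form for change in either direction called 134.

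Named genes followed a fixed rule. It took the 12 largest called rises and 8 largest called falls of each condition against control whose arrays lay outside the range of the control arrays. In every other contrast it took the 8 largest rises and 6 largest falls. A fixed set of genes of IL36 and IL17 biology and of the epidermis was always eligible, as were the 4 members of each list with the largest change. Genes named outside the rule are said to be so.

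The scripts were tested on simulated data with the real means and variances. For combination against control, with 200 of 12463 genes changed, 82% of genes changed by 0.5 log2 and 99% of those changed by 1 were recovered, and 5.24% of the calls were false. For the interaction the shares were 60% and 97%, with 3.09% false calls. With IL36G set equal to control, limma made 0 calls in 12463 genes. The linear-sum test was run on 200 genes, with equal numbers simulated above the sum and at the sum. It called 100% of those above and 1% of those at the sum. These genes were not first chosen as higher than with each single cytokine, so the shares do not cover that choice. In the list test, the 1 shifted list was called and 0 others of the 21 were. The simulated genes varied independently of each other, so this does not test the list calls under correlation between genes.

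Comparisons against control share the 3 control arrays. Chance values were therefore taken from 100 simulations of unchanged groups against shared controls. RNA quality was read from the Affymetrix probe sets for the 3' and 5' ends of ACTB and GAPDH and from the spiked-in transcripts, with exact permutation tests against control that cannot go below 0.1.

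Alternatives tried were no filter or a stricter one at the 60th percentile, the mean or the most variable probe set of a gene, all probe sets singly, quantile normalization, median centring, low values raised to the array median, a trended and robust variance, array quality weights, and only the compared groups in the fit. Further alternatives were cutoffs of 1.5-fold, 2-fold and adjusted p below 0.01, the interaction in place of the linear sum, an estimated correlation or fry for the lists, and leaving out each array in turn. Array weights were estimated gene by gene, because the REML estimate did not converge and gave 1 array an extreme weight. An alternative without IL17A replicate 5 and combination replicate 12 was added after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.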

Results

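Gene expression was measured on 12 arrays in cultured human keratinocytes, the main cell type of the epidermis. The cells received medium, IL36G, IL17A or both cytokines, with 3 arrays in each of the 4 groups. IL36G is a cytokine of the interleukin family that epidermal cells release in inflammation, and IL17A is a T cell cytokine; both are linked to psoriasis. The doses were 100 ng/ml for IL36G and 200 ng/ml for IL17A, alone and together. The title of the series names cooperation of the cytokines and a response like that of psoriasis, so the comparisons below ask what each cytokine changed, what the combination changed, and how far the combination departed from the single cytokines. Values are log2 expression levels, and 12463 genes were tested.

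Each of the 12 arrays was nearest, by Euclidean distance over the tested genes, to an array of its own group. Correlations across genes within a group ran from 0.9971 to 0.9976 for control, 0.9983 to 0.9985 for IL36G, 0.9933 to 0.997 for IL17A and 0.9958 to 0.9985 for the combination. The first 3 principal components held 63.8%, 14.4% and 7.53% of the variance. The 3'-to-5' difference of ACTB, a measure of RNA degradation, was 1.53 ± 0.16 log2 (SD, n = 3) in control, 1.49 ± 0.05 with IL36G, 1.47 ± 0.08 with IL17A and 1.71 ± 0.24 with the combination, whose replicate 12 had the highest value of 1.98. The exact permutation p values against control lay between 0.3 and 0.9 for ACTB and GAPDH, and the smallest p that 3 arrays against 3 allow is 0.1. Among 10 housekeeping genes the median log2 fold change against control was -0.02 with IL36G and -0.03 with IL17A and with the combination, while the means were 0.01, 0.01 and -0.01.

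**Figure D1:**
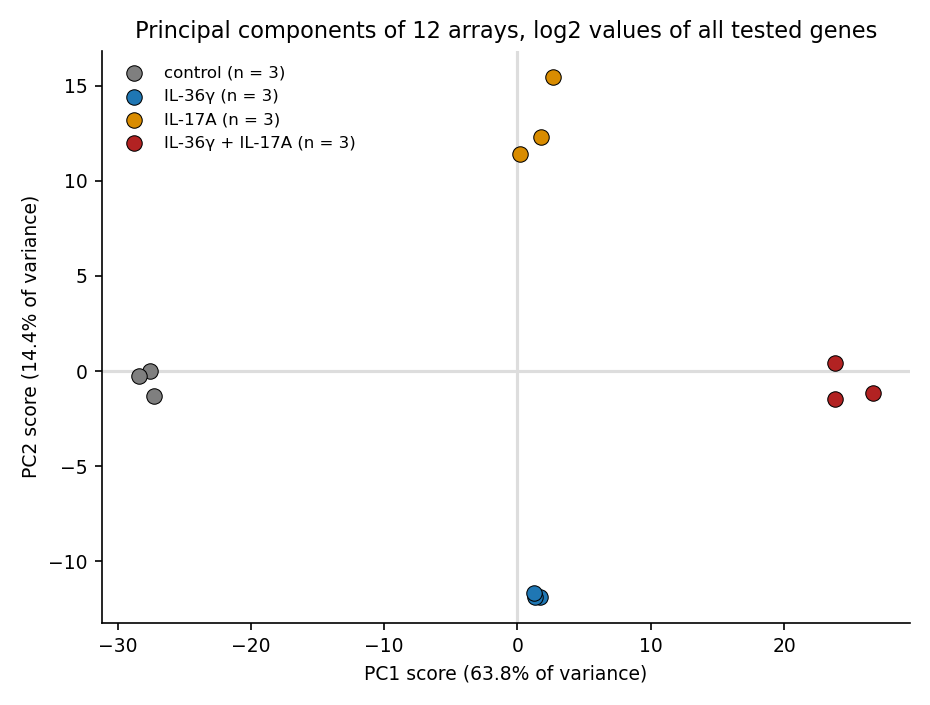
Scores of the 12 arrays on the first 2 principal components of the log2 values of all tested genes, 1 point per array, coloured by condition. The first component holds 63.8% of the variance and the second 14.4%, and the arrays of a condition lie together.

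The first question was what IL36G alone changed. Transcripts of chemokines that attract neutrophils, antimicrobial proteins, cytokines and proteases rose, and genes of the cell cycle fell. The largest rises were those of SERPINA3, an inhibitor of neutrophil proteases (6.49 ± 0.09, adjusted p = 1.53e-12), and S100A7A, an antimicrobial protein of inflamed epidermis (6.40 ± 0.12). SERPINA3 went from 5.64 ± 0.19 (SD, n = 3) in control to 12.13 ± 0.05. The complement component CFB rose by 4.46 ± 0.10, the hyaluronan-binding TNFAIP6 by 4.60 ± 0.26 and the T cell chemoattractant CCL5 by 3.92 ± 0.13. The largest falls were those of the keratin KRT77 (-2.01 ± 0.17), the carboxypeptidase CPVL (-1.67 ± 0.12), DAPL1 (-1.60 ± 0.13) and the matrix protein POSTN (-1.56 ± 0.14).

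Of the neutrophil chemokines, 7 of 7 tested rose with IL36G (7 adjusted over the list alone), with CXCL8 at 3.78 ± 0.20 and CXCL6 at 3.75 ± 0.16 (camera adjusted p = 9.48e-13). Of 10 other chemokines, 7 rose and 2 fell (7 and 2 adjusted over the list alone). CCL20, which attracts Th17 cells, rose by 3.68 ± 0.18 and CXCL11, a ligand of CXCR3, by 3.10 ± 0.21 (camera adjusted p = 1.90e-06). Of 15 antimicrobial proteins, 14 rose (14 adjusted over the list alone), among them S100A7 by 3.81 ± 0.09, S100A12 by 3.80 ± 0.11 and the iron-sequestering LCN2 by 2.90 ± 0.07 (adjusted p = 3.86e-24). Of 10 ligands of the IL-1 family, 9 rose (9 and 1 fall adjusted over the list alone). They included the IL36G transcript itself at 2.59 ± 0.08 and the antagonist IL36RN at 1.51 ± 0.06 (adjusted p = 3.11e-10). Of 23 other cytokines, 17 rose (17 and 1 fall adjusted over the list alone), with IL19 at 2.54 ± 0.16 and IL6 at 2.41 ± 0.17 (adjusted p = 1.33e-12).

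NF-kB targets and feedback genes rose in 17 of 19 cases (18 adjusted over the list alone), including TNFAIP2 at 2.56 ± 0.09, the adhesion molecule ICAM1 at 1.60 ± 0.07 and the inhibitor TNFAIP3 at 1.11 ± 0.10 (camera adjusted p = 9.17e-18). Of 24 proteases and inhibitors, 18 rose and 2 fell with IL36G (21 and 2 adjusted over the list alone), with the elastase MMP12 at 3.97 ± 0.10 and MMP7 at 3.44 ± 0.07 (adjusted p = 9.17e-18). Of 38 genes typical of psoriasis plaque keratinocytes, a list that shares members with those above, 34 rose (34 adjusted over the list alone; adjusted p = 3.31e-42). Of 7 SPRR genes, which encode precursors of the cornified envelope, 5 rose (5 adjusted over the list alone), with SPRR2G at 1.85 ± 0.09 (adjusted p = 1.63e-10). Among 29 genes of late differentiation, 12 rose and 5 fell (13 and 5 adjusted over the list alone). The cross-linking enzyme TGM1 rose by 1.85 ± 0.08 and ALOX12B by 1.65 ± 0.09. Camera gave that list an adjusted p of 0.00171, and an adjusted p = 0.465 with an estimated correlation.

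Of 30 proliferation genes, 24 fell with IL36G (27 adjusted over the list alone), with a median of -0.31. The mitotic kinesin KIF20A fell by 0.62 ± 0.06, CENPF by 0.62 ± 0.05 and MKI67 by 0.53 ± 0.06 (camera adjusted p = 4.00e-17). Among 23 interferon-stimulated genes, 5 rose and 2 fell (5 and 2 adjusted over the list alone), with BST2 at 1.44 ± 0.16 and OASL at 0.91 ± 0.10, and the list as a whole was not called (adjusted p = 0.24). Among 14 receptors and adapters, 4 rose (5 adjusted over the list alone). The kinase IRAK2 rose by 1.06 ± 0.10, whereas the receptor subunit IL1RL2 was at -0.04 ± 0.14 and IL17RA at 0.03 ± 0.04 (adjusted p of the list 0.0118). Of 5 tested fibroblast markers, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with LUM at 2.66 ± 0.15 and COL1A2 at -0.78 ± 0.12 beside POSTN (adjusted p = 0.836, downward, with a median of -0.18 and a mean of 0.07).

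In total 2282 genes were called between IL36G and control, 1163 higher and 1119 lower, or 18.3% of those tested. At least 2-fold changes numbered 122 rises and 25 falls. Over all tested genes the arrays of the groups did not overlap for 41.6%, where chance gives 10% for 3 against 3. Folds of dim genes depended on how low values were treated: with values raised to the array median, the rise of SERPINA3 was 5.35, that of S100A7A 5.31, that of TNFAIP6 2.14, that of MMP12 2.31, that of CXCL11 1.84, that of IL19 1.34 and that of BST2 0.93. With the mean of a gene's probe sets CFB was at 2.31, TNFAIP2 at 1.35, IRAK2 at 0.42 and POSTN at -1.03.

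**Figure D2:**
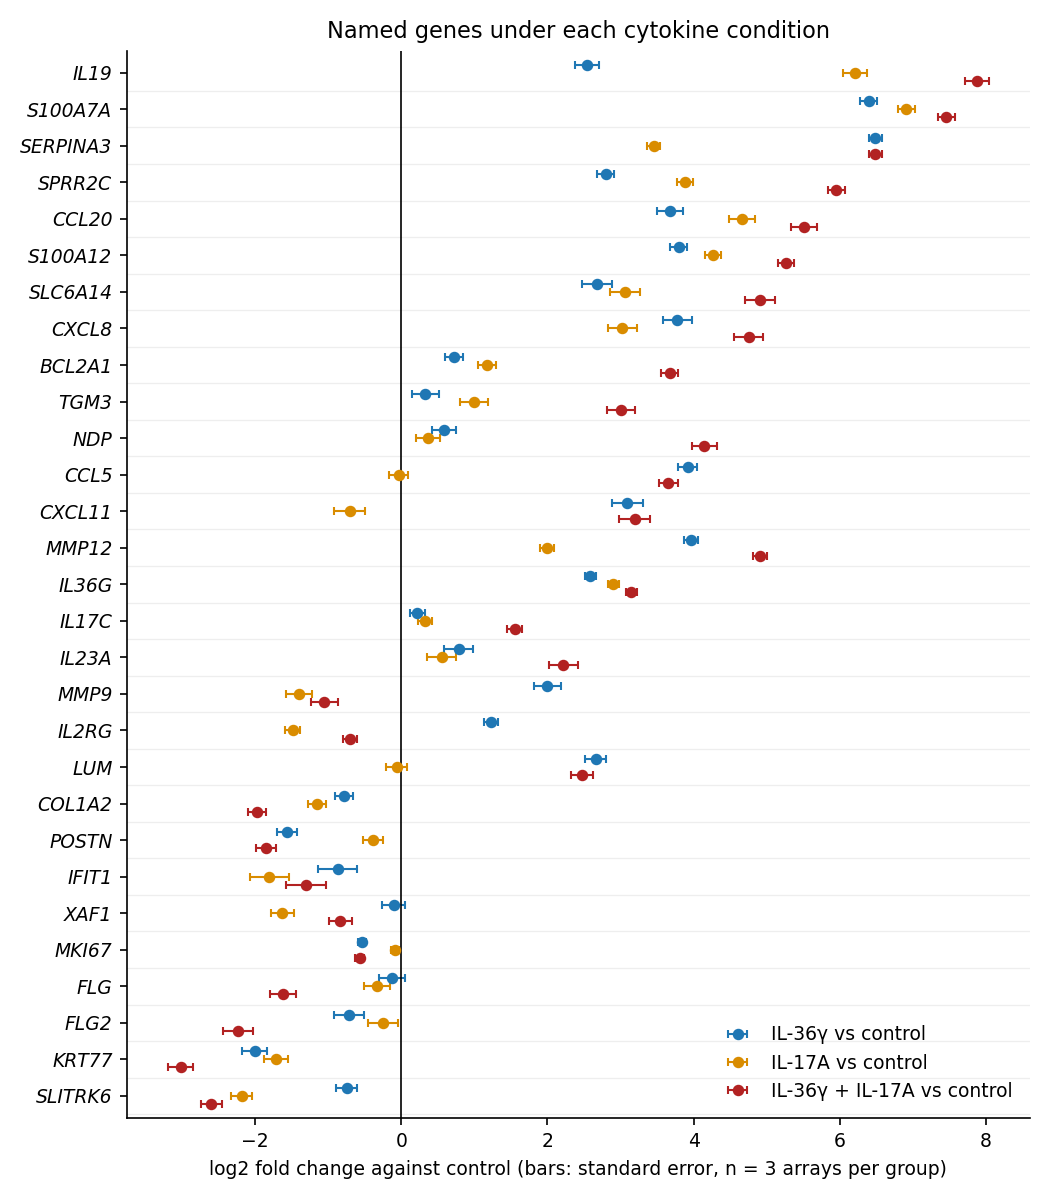
Log2 fold changes against control of named genes for IL36G, IL17A and the combination, with standard errors as bars (n = 3 arrays per group). IL19 lies at 2.54 with IL36G, 6.21 with IL17A and 7.88 with the combination, and SERPINA3 at 6.49, 3.45 and 6.49.

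The second question was what IL17A alone changed. Many antimicrobial, neutrophil chemokine and cornified envelope transcripts rose, and 21 of 23 interferon-stimulated genes fell. The list of the latter had a camera adjusted p of 1.08e-11, and an adjusted p = 0.134 with an estimated correlation. The largest rises were those of S100A7A (6.91 ± 0.12) and IL19, a cytokine of the IL-10 family (6.21 ± 0.16, adjusted p = 2.40e-10). IL19 was at 5.58 ± 0.33 (SD, n = 3) in control and 11.79 ± 0.25 with IL17A. CCL20 rose by 4.67 ± 0.18, the protease inhibitor SERPINB4 by 3.81 ± 0.07, the ammonium transporter RHCG by 3.42 ± 0.06 and the amino acid transporter SLC6A14 by 3.06 ± 0.20. Among the largest falls were those of SLITRK6 (-2.18 ± 0.14), the antiviral gene IFIT1 (-1.81 ± 0.27), IFI44L (-1.75 ± 0.24), KRT77 (-1.71 ± 0.17) and XAF1 (-1.63 ± 0.15).

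Of 15 antimicrobial proteins, 13 rose with IL17A (14 adjusted over the list alone), including S100A12 at 4.26 ± 0.11, S100A7 at 3.87 ± 0.09 and LCN2 at 3.00 ± 0.07 (camera adjusted p = 4.72e-21). The 7 neutrophil chemokines rose (7 adjusted over the list alone), with CXCL6 at 3.44 ± 0.16 and CXCL8 at 3.02 ± 0.20 (adjusted p = 4.55e-10). Other chemokines went both ways: 3 rose and 3 fell of 10 (3 and 3 adjusted over the list alone). CX3CL1, a membrane-bound chemokine, fell by 1.09 ± 0.12. That list had a median of -0.05, a mean of 0.26 and an adjusted p of 0.873. Of the IL-1 family ligands, 8 of 10 rose and 1 fell (8 and 1 adjusted over the list alone), with the IL36G transcript at 2.90 ± 0.08 and IL1B at 1.72 ± 0.15 (adjusted p = 4.83e-09). Other cytokines rose in 13 of 23 cases and fell in 1 (14 and 3 adjusted over the list alone; adjusted p = 9.61e-06).

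NF-kB targets rose in 10 of 19 cases and fell in 3 with IL17A (10 and 5 adjusted over the list alone), with the kinase MAP3K8 at 1.79 ± 0.13 and the NF-kB cofactor NFKBIZ at 1.26 ± 0.10. The list had an adjusted p of 0.00193, and an adjusted p = 0.125 with an estimated correlation. Of 38 psoriasis plaque genes, 33 rose (36 adjusted over the list alone; adjusted p = 3.31e-42). SPRR genes rose in 5 of 7 cases (5 adjusted over the list alone), with SPRR2G at 2.00 ± 0.09 and SPRR2B at 1.91 ± 0.04 (adjusted p = 3.15e-10). Late differentiation genes rose in 15 of 29 cases and fell in 2 (15 and 4 adjusted over the list alone), with ALOX12B at 2.38 ± 0.09, TGM1 at 2.27 ± 0.08 and KRT78 at 1.66 ± 0.12. That list had an adjusted p of 1.93e-05, and an adjusted p = 0.303 with an estimated correlation. Proteases and inhibitors rose in 16 of 24 cases and fell in 4 (16 and 4 adjusted over the list alone), with the plasminogen activator PLAT at 2.16 ± 0.09 (adjusted p = 6.62e-10).

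Of 23 interferon-stimulated genes, 21 fell with IL17A (21, and 1 rise, adjusted over the list alone), with a median of -0.93. Besides IFIT1, IFI44L and XAF1, the gene IFI44 fell by 1.51 ± 0.20. The call of the list by camera (adjusted p = 1.08e-11) was lost with an estimated correlation (adjusted p = 0.134). Proliferation genes fell in 2 of 30 cases (1 adjusted over the list alone), with a median of -0.03 and an adjusted p of 0.2. Of 11 basal keratinocyte genes, 5 fell (5 adjusted over the list alone), with the integrin subunit ITGA3 at -0.32 ± 0.04 and the keratin KRT15 at -0.24 ± 0.05 (adjusted p = 0.011). Among 20 genes of unfolded protein and amino acid stress, 8 rose and 3 fell (8 and 4 adjusted over the list alone), with CHAC1 at 1.06 ± 0.13 and ATF3 at 0.73 ± 0.06. That list had an adjusted p of 0.0494, and an adjusted p = 0.479 with an estimated correlation. Of 15 heat shock and immediate early genes, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with EGR3 at 1.11 ± 0.11. Their median was -0.01 and their mean 0.13, and the list was not called (adjusted p = 0.2). COL1A2, a fibroblast marker, fell by 1.15 ± 0.12, and LUM was at -0.06 ± 0.15 without a call.

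Between IL17A and control 2866 genes were called, 1281 higher and 1585 lower, or 23% of those tested. At least 2-fold changes numbered 129 rises and 48 falls, and the groups did not overlap for 34.7% of all tested genes, where chance gives 10%. The IL17A arrays were the most spread, with a median SD per gene of 0.091 against 0.062 in control. With only the 6 compared arrays in the fit, 1824 genes were called. With low values raised to the array median, S100A7A was at 5.82 and IL19 at 5.01.

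The third question was what the combination changed against control. Here 5052 genes were called, 2538 higher and 2514 lower, or 40.5% of those tested. Genes changed at least 2-fold were 350 higher and 117 lower, and the groups did not overlap for 54.6% of all tested genes, where chance gives 10%. The largest rises were those of IL19 (7.88 ± 0.16, adjusted p = 1.52e-11), S100A7A (7.46 ± 0.12), SERPINA3 (6.49 ± 0.09), SPRR2C (5.95 ± 0.12), CCL20 (5.52 ± 0.18), COXFA4L3 (5.33 ± 0.14), VNN3P (5.31 ± 0.13) and S100A12 (5.26 ± 0.11). The largest falls were those of KRT77 (-3.02 ± 0.17), SLITRK6 (-2.60 ± 0.14), DAPL1 (-2.37 ± 0.13), the cornified layer protein FLG2 (-2.24 ± 0.20), the estrogen sulfotransferase SULT1E1 (-2.17 ± 0.13) and the basement membrane protein NID1 (-2.15 ± 0.16).

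Neutrophil chemokines rose in 7 of 7 cases with the combination (7 adjusted over the list alone), with CXCL8 and CXCL6 both at 4.75 (SE 0.20 and 0.16; camera adjusted p = 8.31e-09). Of 10 other chemokines 8 rose and 2 fell (8 and 2 adjusted over the list alone), with CCL5 at 3.66 ± 0.13 beside CCL20 (adjusted p = 0.000381). Antimicrobial proteins rose in 14 of 15 cases (15 adjusted over the list alone), with S100A7 at 4.07 ± 0.09 and LCN2 at 3.54 ± 0.07 (adjusted p = 1.36e-17). The IL-1 family list had 8 rises and 1 fall in 10 (8 and 1 adjusted over the list alone), with IL1F10 at 3.37 ± 0.12, the IL36G transcript at 3.15 ± 0.08 and IL36RN at 2.62 ± 0.06 (adjusted p = 1.08e-06). Other cytokines rose in 18 of 23 cases and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 5.89e-09). IL6 rose by 3.73 ± 0.17, IL23A, a subunit of the cytokine that sustains Th17 cells, by 2.21 ± 0.20, and IL17C, an epithelial cytokine of the IL17 family, by 1.55 ± 0.10.

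NF-kB targets rose in 15 of 19 cases and fell in 1 with the combination (15 and 1 adjusted over the list alone), with TNFAIP2 at 3.28 ± 0.09 and NFKBIA at 1.34 ± 0.06 (camera adjusted p = 7.62e-09). Psoriasis plaque genes rose in 35 of 38 cases (35 adjusted over the list alone; adjusted p = 1.34e-30), including SERPINB4 at 4.36 ± 0.07. Of the 5 wound and plaque keratins 1 was tested, KRT16, which was at -0.03 ± 0.04 without a call. Proteases and inhibitors rose in 20 of 24 cases and fell in 4 (20 and 4 adjusted over the list alone), with MMP7 at 3.63 ± 0.07 and PLAT at 3.62 ± 0.09 (adjusted p = 4.47e-12). SPRR genes rose in 5 of 7 cases (5 adjusted over the list alone; adjusted p = 2.69e-07). Receptors and adapters rose in 5 of 14 cases and fell in 1 (5 and 1 adjusted over the list alone), with IRAK2 at 1.31 ± 0.10 and IL1RAP at -0.59 ± 0.11. That list had an adjusted p of 0.0475, and an adjusted p = 0.101 with an estimated correlation.

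Late differentiation genes moved in both directions with the combination: 15 of 29 rose and 10 fell (15 and 11 adjusted over the list alone). ALOX12B rose by 3.25 ± 0.09, TGM3 by 3.00 ± 0.19 and TGM1 by 2.94 ± 0.08. Among the members that fell were filaggrin (FLG) at -1.62 ± 0.18, FLG2 at -2.24 ± 0.20 and KRT10 at -0.30 ± 0.08. The list had a camera adjusted p of 0.0315, and an adjusted p = 0.626 with an estimated correlation. Proliferation genes fell in 27 of 30 cases (28 adjusted over the list alone), with a median of -0.35, KIF20A at -0.66 ± 0.06 and TOP2A at -0.61 ± 0.04 (adjusted p = 5.66e-11). Basal genes fell in 5 of 11 cases (5 adjusted over the list alone), with KRT15 at -0.36 ± 0.05; that list had an adjusted p of 0.0194, and an adjusted p = 0.0655 with an estimated correlation. Glycolysis and hypoxia genes rose in 16 of 24 cases and fell in 1 (16 and 2 adjusted over the list alone), with the enolase ENO2 at 1.40 ± 0.09 and the oxygen sensor EGLN3 at 1.08 ± 0.07 (adjusted p = 4.96e-05). Targets of NRF2 rose in 9 of 13 cases and fell in 3 (9 and 3 adjusted over the list alone), with HMOX1 at 0.88 ± 0.07 and NQO1 at -0.77 ± 0.04 (adjusted p = 0.113). Of 14 cholesterol synthesis genes 3 rose and 1 fell (3 rises adjusted over the list alone), with DHCR7 at 0.25 ± 0.04 (adjusted p = 0.175).

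Interferon-stimulated genes went both ways with the combination, with 5 rises and 9 falls in 23 (5 and 9 adjusted over the list alone). OASL rose by 1.75 ± 0.10 and IFIT1 fell by 1.30 ± 0.27. Their median was -0.08 and their mean 0.02, and the list was not called (camera adjusted p = 0.764). Markers of other cells were mostly below the filter. Of 11 leukocyte markers only ITGAM was tested, and it fell by 0.62 ± 0.16. It was at 0.69 ± 0.16 with IL36G alone (adjusted p = 0.0116) and -0.63 ± 0.16 with IL17A alone (adjusted p = 0.016). The first call was lost without control replicate 1 (0.60) or IL36G replicate 7 (0.61), and the second without control replicate 2 (-0.60) or 3 (-0.57). The endothelial list had 0 tested members of 6, and of the melanocyte list 2 were tested, with PMEL at 0.12 ± 0.09 without a call and 1 member called lower (1 adjusted over the list alone). Fibroblast markers parted: LUM rose by 2.48 ± 0.15 while COL1A2 fell by 1.97 ± 0.12 and POSTN by 1.85 ± 0.14. Of the 5 tested, 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.283). The ACTB 3'-to-5' difference was highest on combination replicate 12, with 1.98. Without that array and IL17A replicate 5, 4872 genes were called between the combination and control. With low values raised to the array median, IL19 was at 6.67, S100A7A at 6.37, SERPINA3 at 5.34 and SPRR2C at 4.02. With the mean of a gene's probe sets TNFAIP2 was at 1.73, IRAK2 at 0.57 and POSTN at -1.16.

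**Figure D3:**
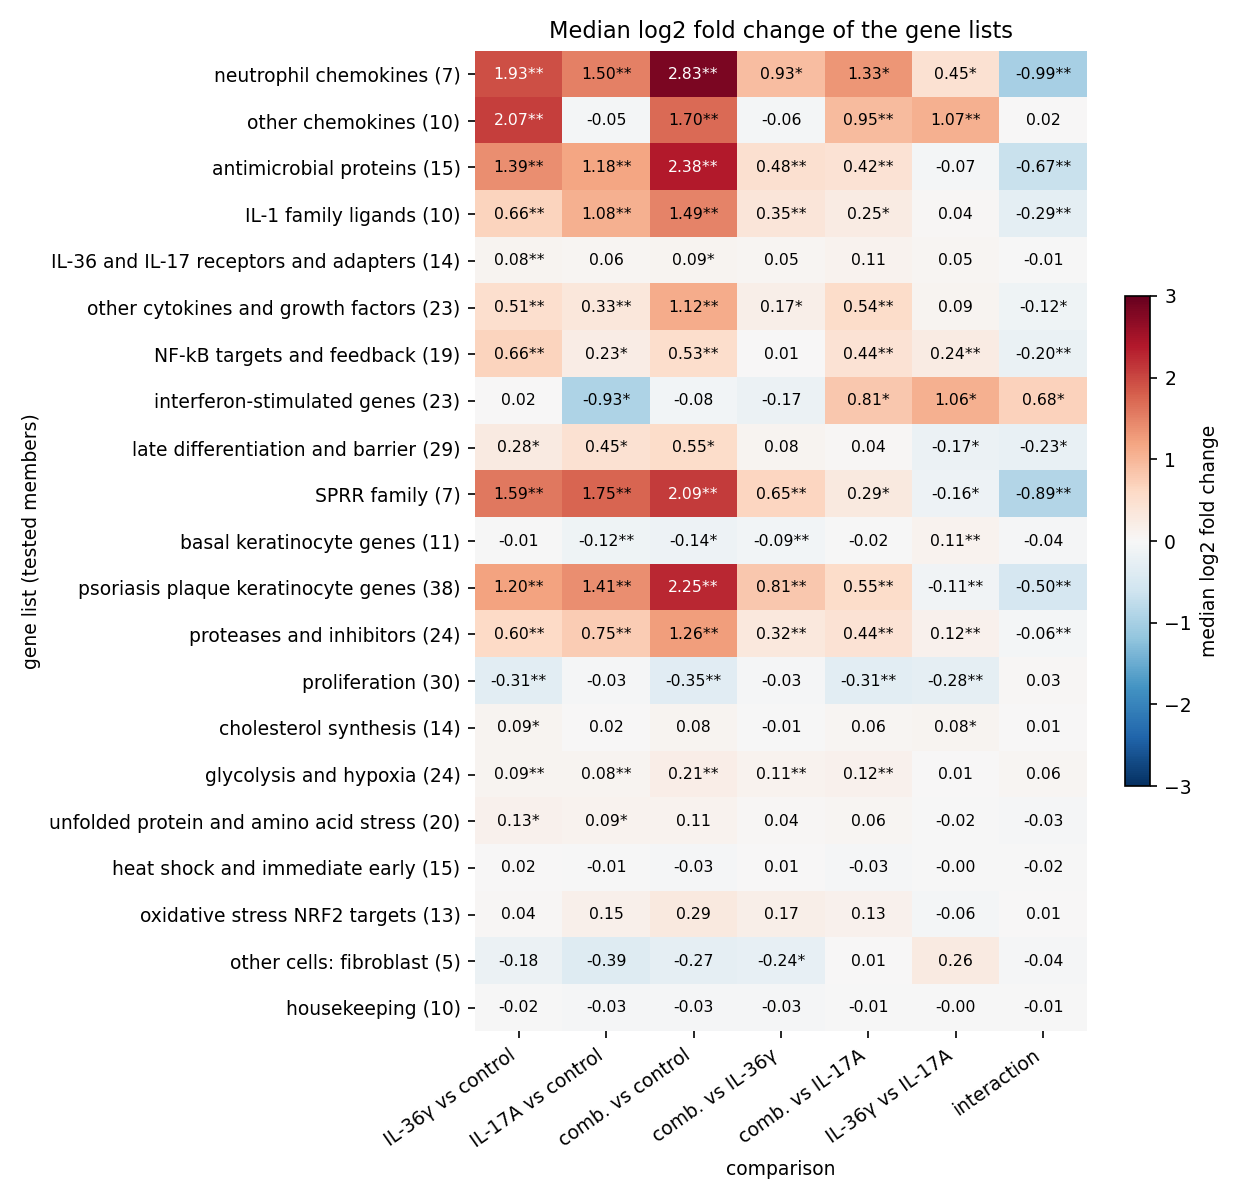
Median log2 fold change of the fixed gene lists in each comparison, with the number of tested members in brackets. One star marks a list called by camera with the preset correlation and a pair of stars one also called with an estimated correlation, as for the psoriasis plaque list against control (1.20 with IL36G, 1.41 with IL17A and 2.25 with the combination).

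The comparison of the combination with IL36G alone asked what adding IL17A changed. IL19 was higher by 5.33 ± 0.16 (adjusted p = 1.07e-08), NDP, a secreted ligand of Frizzled receptors, by 3.56 ± 0.17, SPRR2C by 3.15 ± 0.12, the transglutaminase TGM3 by 2.67 ± 0.19 and PLAT by 2.58 ± 0.09. MMP9, a gelatinase, fell by 3.06 ± 0.18, followed by the cytokine receptor chain IL2RG (-1.93 ± 0.10), SLITRK6 (-1.85 ± 0.14), SHISA2 (-1.75 ± 0.11) and FLG2 (-1.52 ± 0.20). FLG was also lower, at -1.50 ± 0.18. Psoriasis plaque genes rose further in 28 of 38 cases (33 adjusted over the list alone), with ATP12A at 2.29 ± 0.09 and SERPINB4 at 1.63 ± 0.07 (camera adjusted p = 1.17e-23). Antimicrobial proteins rose in 11 of 15 cases (14 adjusted over the list alone), with lactoferrin (LTF) at 1.64 ± 0.12 and the complement gene C3 at 1.14 ± 0.13 (adjusted p = 1.63e-11). The 7 neutrophil chemokines rose (7 adjusted over the list alone), with CXCL8 at 0.97 ± 0.20; their adjusted p was 2.49e-05, and an adjusted p = 0.132 with an estimated correlation. NF-kB targets went both ways, with 7 rises and 4 falls in 19 (7 and 5 adjusted over the list alone). MAP3K8 rose by 0.96 ± 0.13 while TRAF1 fell by 0.84 ± 0.07 and ICAM1 by 0.79 ± 0.07 (adjusted p = 0.569). The leukocyte marker ITGAM fell by 1.31 ± 0.16, and the fibroblast marker COL1A2 fell by 1.19 ± 0.12.

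Between the combination and IL36G 2285 genes were called, 1307 higher and 978 lower, with at least 2-fold changes for 111 and 31. The groups did not overlap for 44.2% of all tested genes, where chance gives 10%. The count was 1469 without IL36G replicate 7 and 1503 without IL36G replicate 9, and 4242 with array quality weights. NDP was dim outside the combination, and its difference was 1.59 with low values raised to the array median, where that of IL2RG was -0.99.

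The comparison of the combination with IL17A alone asked what adding IL36G changed. Proteases and NF-kB targets rose, and proliferation genes fell. CXCL11 was higher by 3.90 ± 0.21 (adjusted p = 3.61e-07), NDP by 3.78 ± 0.17, CCL5 by 3.69 ± 0.13, SERPINA3 by 3.04 ± 0.09 and CXCL10 by 3.00 ± 0.36. FLG2 was lower (-1.99 ± 0.20), as were AADACL2 (-1.61 ± 0.21), POSTN (-1.46 ± 0.14) and SULT1E1 (-1.40 ± 0.13). Of 24 proteases and inhibitors, 18 rose (19 and 1 fall adjusted over the list alone), with MMP12 at 2.92 ± 0.10, MMP7 at 2.38 ± 0.07 and the cathepsin CTSS at 1.85 ± 0.10 (camera adjusted p = 1.09e-14). NF-kB targets rose in 15 of 19 cases (15 adjusted over the list alone), with ICAM1 at 1.03 ± 0.07 (adjusted p = 4.55e-10). Of 30 proliferation genes 22 fell (28 adjusted over the list alone), with MKI67 at -0.48 ± 0.06 (adjusted p = 9.17e-18). Of 23 interferon-stimulated genes 18 were higher (20 adjusted over the list alone), with BST2 at 1.84 ± 0.16, IFI44L at 1.78 ± 0.24 and IFITM1 at 1.76 ± 0.16. That list had an adjusted p of 1.31e-12, and an adjusted p = 0.12 with an estimated correlation. Psoriasis plaque genes rose in 27 of 38 cases and fell in 1 (29 and 1 adjusted over the list alone), with ATP12A at 2.16 ± 0.09 and CXCL8 at 1.73 ± 0.20 (adjusted p = 2.72e-16). The fibroblast marker LUM rose by 2.54 ± 0.15 while COL1A2 fell by 0.82 ± 0.12.

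Between the combination and IL17A 2620 genes were called, 1596 higher and 1024 lower, with at least 2-fold changes for 122 and 16. The groups did not overlap for 34% of all tested genes, where chance gives 10%. With only the 6 compared arrays in the fit the count was 1471, and with array quality weights 3940. The CXCL11 difference was 1.95 and that of NDP 1.58 with low values raised to the array median, and POSTN was at -0.89 with the mean of its probe sets.

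The direct comparison of the single cytokines called 1847 genes, 1028 higher with IL36G and 819 higher with IL17A, with at least 2-fold differences for 62 and 9. Groups did not overlap for 33% of all tested genes, where chance gives 10%. Higher with IL36G were CCL5 (3.96 ± 0.13, adjusted p = 6.43e-09), CXCL11 (3.80 ± 0.21), MMP9 (3.40 ± 0.18), CXCL10 (3.17 ± 0.36), SERPINA3 (3.04 ± 0.09) and LUM (2.72 ± 0.15). Higher with IL17A were IL19 (-3.67 ± 0.16 as IL36G minus IL17A), TPRG1 (-1.34 ± 0.12), ENDOU (-1.27 ± 0.08), SERPINB4 (-1.08 ± 0.07) and CCL20 (-0.98 ± 0.18). Of 23 interferon-stimulated genes 21 were higher with IL36G than with IL17A (22 adjusted over the list alone), with IFI44L at 2.06 ± 0.24. That list had a camera adjusted p of 1.36e-19, and an adjusted p = 0.0542 with an estimated correlation. Proliferation genes were lower with IL36G in 22 of 30 cases (26 adjusted over the list alone; adjusted p = 1.36e-17). Psoriasis plaque genes were higher with IL17A in 13 of 38 cases and with IL36G in 3 (15 and 3 adjusted over the list alone; adjusted p = 2.14e-05). The count of called genes was 1142 without IL36G replicate 7, 1120 without replicate 8 and 1190 without replicate 9, and 3303 with array quality weights. The balance turned with these weights (1571 higher with IL36G and 1732 with IL17A) and without IL17A replicate 4 (1096 and 1135). CXCL11 was at 1.85 with low values raised to the array median.

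The overlap between the single cytokines was larger than independent lists give. Of the called genes 691 were higher with both, where 119.5 would be shared by independent lists, and 600 were lower with both, where 142.3 would be. In opposite directions were 63 genes, 59 of them higher with IL36G and lower with IL17A, including MMP9 (2.00 ± 0.18 and -1.40 ± 0.18) and IL2RG (1.23 ± 0.10 and -1.49 ± 0.10), which lie outside the rule for named genes in these comparisons and were chosen after their values were seen. Fold changes against control correlated across genes at 0.726 between IL36G and IL17A, 0.868 between IL36G and the combination and 0.856 between IL17A and the combination, where unchanged groups sharing the controls gave 0.501, 0.5 and 0.5. The covariances were 0.0658, 0.122 and 0.122, against 0.00347, 0.00347 and 0.00348 in the simulation. Genes are not independent replicates. The 3 control arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls. IL36G and the combination shared 1043 rises and 982 falls (236.8 and 225.7 for independent lists), and IL17A and the combination shared 1135 rises and 1151 falls (260.9 and 319.7). The combination called 2004 genes that neither single cytokine called, of which 201 rises and 157 falls also differed from both singles in that direction.

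The last question was how the combination compared with what the single cytokines would give together. In the combination 781 genes were higher than with each single cytokine, and 408 were lower than with each. Of the 781, 765 were also higher than in control. Against the sum of the increments on the unlogged scale, 296 of the 781 lay above, 12 lay below and 473 were not called. The choice of the 781 favours high combination values on the same arrays, and in a test added after seeing the data, over the 12445 tested genes with a sum above 0, the counts were 147 above and 35 below. On the log2 scale described below, 69 of the 781 were called above the sum of the single effects and 47 below. NDP lay 3.30 ± 0.19 log2 above the linear sum, and 1.60 above it with low values raised to the array median, since it was below that median outside the combination. NDP was at 4.21 ± 0.22 (SD, n = 3) in control, 4.79 ± 0.19 with IL36G, 4.57 ± 0.30 with IL17A and 8.35 ± 0.24 with the combination. Other genes above the sum were the survival factor BCL2A1 (2.13 ± 0.12, and 0.97 with low values raised), TGM3 (1.83 ± 0.20), ATP12A (1.61 ± 0.09), COXFA4L3 (1.61 ± 0.12), SPRR2C (1.58 ± 0.10), IL19 (1.57 ± 0.16), LTF (1.51 ± 0.12), SLC6A14 (1.13 ± 0.18), IL23A (1.09 ± 0.21) and IL17C (1.05 ± 0.12). CCL20 was at 0.30 ± 0.16 and S100A7A at -0.21 ± 0.10, both without a call. With low values raised, S100A7A was called below the linear sum (-0.20 ± 0.05, adjusted p = 0.00486). In that setting the IL36G transcript (-0.49), SPRR2B (-0.44), LCN2 (-0.32) and SPRR3 (-0.24) were also called below it.

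On the log2 scale, where the sum of the single effects corresponds to a product of folds, the interaction was called for 241 genes, 145 above the sum and 96 below. At least 2-fold departures numbered 23 above and 29 below, and at least 1.5-fold ones 60 and 63. NDP lay above by 3.19 ± 0.24 (adjusted p = 1.78e-05), BCL2A1 by 1.78 ± 0.17, TGM3 by 1.68 ± 0.27, LTF by 1.36 ± 0.16, the protease inhibitor SERPINA1 by 1.35 ± 0.13 and IL17C by 1.00 ± 0.14. Below the sum lay S100A7A (-5.85 ± 0.16, adjusted p = 4.65e-09), S100A7 (-3.61 ± 0.12), SERPINA3 (-3.45 ± 0.13), CCL20 (-2.83 ± 0.25), S100A12 (-2.80 ± 0.16), LCN2 (-2.36 ± 0.10) and the IL36G transcript (-2.34 ± 0.11). S100A7 reached 14.01 ± 0.01 (SD, n = 3) with IL36G, 14.07 ± 0.09 with IL17A and 14.27 ± 0.02 with both, on arrays whose highest value was 14.67. Among 15 antimicrobial proteins 10 lay below the sum and 1 above (11 and 2 adjusted over the list alone; camera adjusted p = 1.38e-20), and among 38 psoriasis plaque genes 19 below and 1 above (23 and 4 adjusted over the list alone; adjusted p = 7.28e-32). Interferon-stimulated genes lay above the sum in 5 of 23 cases (19 adjusted over the list alone), with a median of 0.68. That list had an adjusted p of 9.97e-16, and an adjusted p = 0.0826 with an estimated correlation. Glycolysis and hypoxia genes had 1 member above (2 adjusted over the list alone; adjusted p = 0.0529), and proliferation genes a median of 0.03 (adjusted p = 0.77).

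The interaction count depended on single arrays. It was 130, 133 and 140 without IL36G replicates 9, 7 and 8, 136 and 155 without combination replicates 10 and 12, and 149 without control replicate 3, where 72 lay above the sum and 77 below. It was 597 with array quality weights and 159 without the filter on dim probe sets. With low values raised to the array median the NDP interaction was 1.60 and that of BCL2A1 0.97, and with the mean of a gene's probe sets that of S100A7A was -3.80. Any difference among the 4 groups was found by the F test for 5127 genes.

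**Figure D4:**
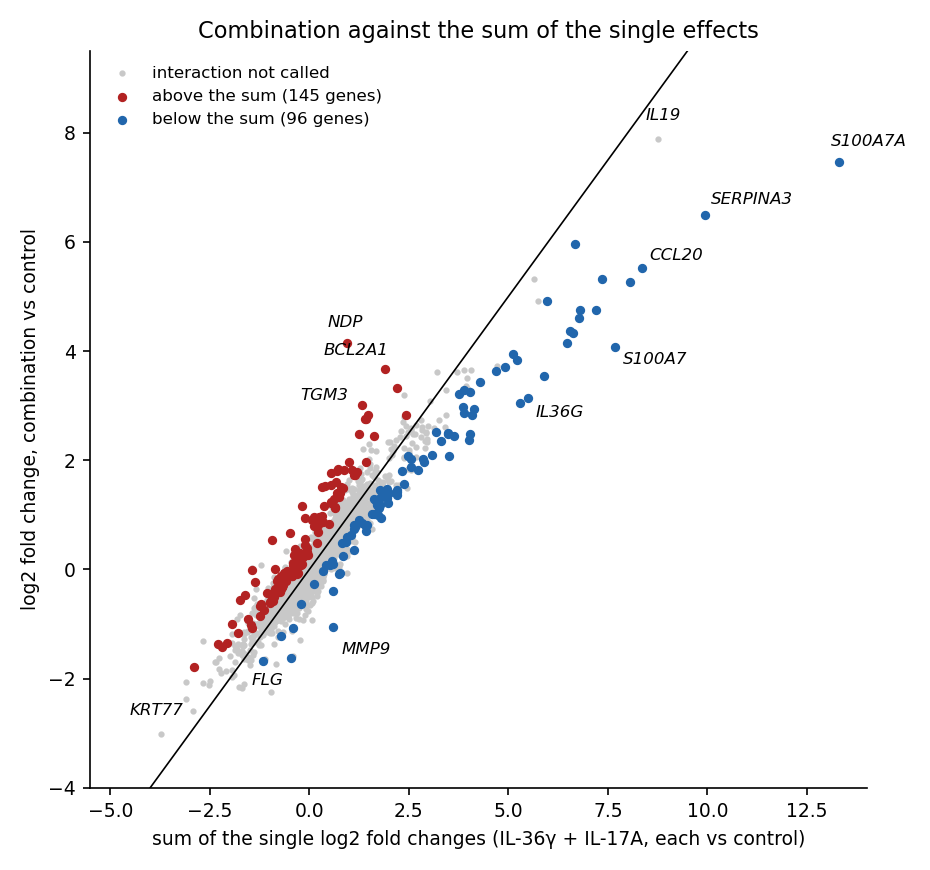
Log2 fold change of the combination against the sum of the single log2 fold changes, each against control, 1 point per tested gene; coloured points have a called interaction. Of these, 145 genes lie above the sum, led by NDP at 3.19, and 96 lie below, led by S100A7A at -5.85.

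**Figure D5:**
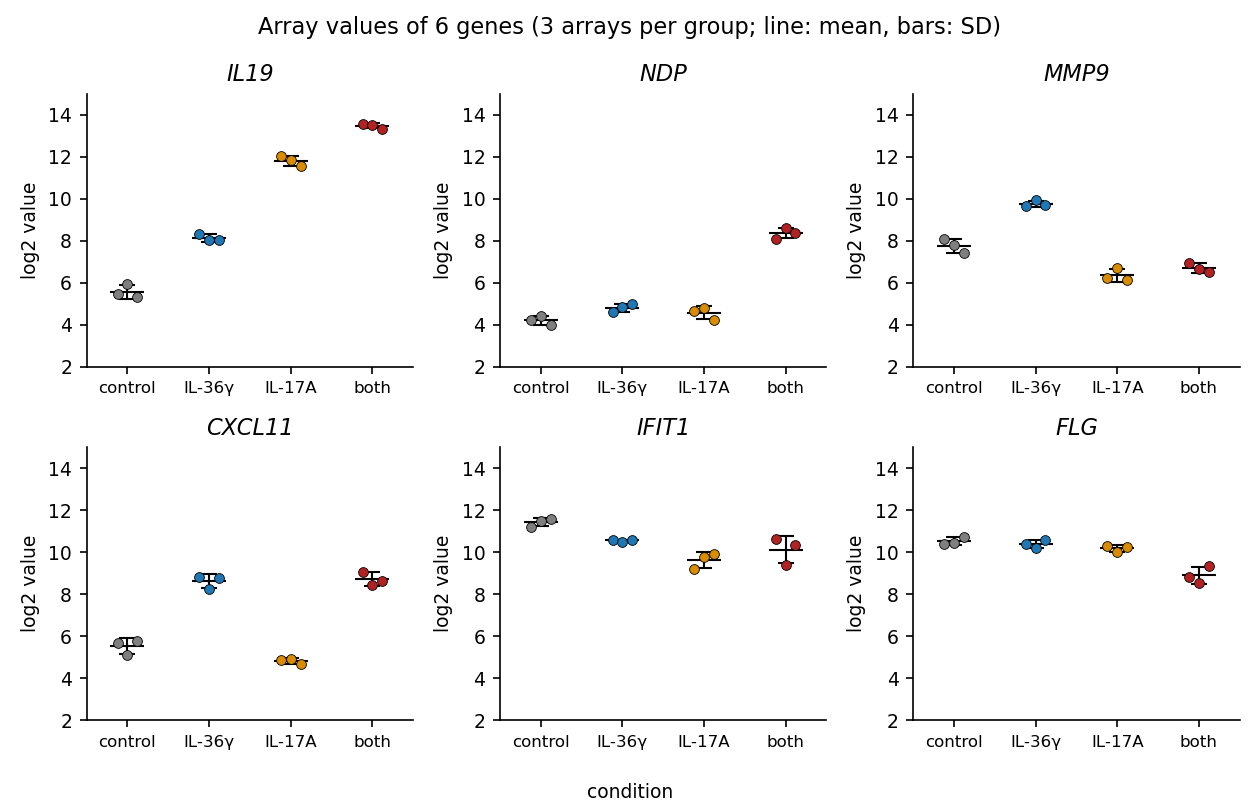
Log2 values of 6 genes on each of the 12 arrays (points), with the mean (line) and SD (bars) of each condition, n = 3. NDP has a mean of 8.35 with the combination and at most 4.79 otherwise, and MMP9 one of 9.75 with IL36G and 6.70 with the combination.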

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

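The tests of technical explanations below were chosen after the results they concern were seen; the splits of the arrays were planned.

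On the log2 scale the effect of IL17A differed with and without IL36G for 241 genes, by the interaction test. Of these, 14 genes had IL17A effects called in opposite directions in the absence and presence of IL36G, such as SERPINA1 (-0.44 ± 0.09 and 0.91 ± 0.09), SULF1 (-0.27 ± 0.07 and 0.51 ± 0.07) and XDH (-0.30 ± 0.06 and 0.37 ± 0.06). The effect of IL36G was called in opposite directions without and with IL17A for 13 genes, such as the alarmin IL33 (0.27 ± 0.08 and -0.48 ± 0.08) and KLHDC7B (0.64 ± 0.11 and -0.35 ± 0.11). These genes were chosen after their values were seen, apart from SERPINA1 and IL33. Probe sets outside the gene tests also held signal: 358 of 1138 with several gene symbols and 1167 of 3356 with no symbol were called between the combination and control, with at least 2-fold rises for 23 and 37 and falls for 7 and 55.

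The count of genes with any group difference was 5127. It was matched by 1 of 100 splits of the 12 arrays into 4 groups of 3, the real one. The highest other was 1217, so the real grouping of the arrays stood apart from the splits drawn. The arrays of a group may be technical repeats, so the splits cannot exclude chance differences between cultures. The count of genes above both single cytokines was matched by 1 of 100 (781, highest other 602). The interaction count was matched by 2 of 100 (241, highest other 1402), the count above the linear sum by 2 (296, highest other 599) and the count of list tests by 2 (85, highest other 88), the real split included. Splits that mix the conditions carry their strong differences into the groups, so for these 4 counts they give no measure of chance, and it is not excluded by them. The split with 1402 genes, several times the real interaction count, points to the structure of the conditions: its interaction contrast gave control a weight of 1 and the combination one of -1, with 0.333 for IL17A and -0.333 for IL36G. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and in each 1 split, the real one, reached the real count. The real counts and the highest others were 2282 and 1 for IL36G against control, 2866 and 1 for IL17A, 5052 and 0 for the combination, 2285 and 0 for the combination against IL36G, 2620 and 1 against IL17A, and 1847 and 0 between the single cytokines.

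Of 80 genes at least 2-fold higher with each single cytokine, 75 had an interaction below 0, with a median of -0.82, and 78 rose more in the combination than with the stronger single cytokine. Noise in the shared control arrays was tested 2 times. In 100 simulations with additive effects and separate noise on each array, the lowest median was -0.07. After that result was known, genes were chosen without 1 control array and measured against it. That gave medians of -0.86, -0.84 and -0.67, and the highest, -0.67, is the deciding value. Both tests argue against separate noise of single control arrays as the cause. A deviation common to the control arrays would escape both. The held-out test also chose its genes on the single-cytokine arrays that enter the interaction. Compression of signals near the top of the array scale cannot be told apart from a smaller response: the 20 genes with a combination mean below 10 had a median of -0.51 (95% bootstrap interval -0.70 to -0.18), and the 60 brighter genes one of -0.90. The upper bound missed the limit set for the test narrowly. A shared ceiling of the cells' own response may also account for it and was not tested.

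Interferon-stimulated genes had a list median of -0.93 with IL17A alone, with 21 of 23 called lower, though the list was not called with an estimated correlation (adjusted p = 0.134). The list median lay 1.06 higher on the IL36G arrays than on those of IL17A, and 0.81 higher in the combination. Both of these groups received IL36G. High levels in the control arrays, offset by a rise with IL36G, therefore cannot be told apart from a fall with IL17A. On the IL36G arrays the median of the list minus control ran from -0.05 to 0.06. IFIT1 was lower there, at 10.51 to 10.59 against 11.2 to 11.59 in control, so the list median does not speak for that gene. A single IL17A array is argued against by the medians with 1 of them left out, which ran from -1.11 to -0.79, while a shift of all genes was not testable, since the quantile normalization holds the median over all tested genes (-0.00857) near 0. Batches and scan dates are not given, so a batch shared by the IL17A arrays cannot be told apart from the cytokine, and an effect of IL17A on interferon signalling stays open as a hypothesis that was not tested further.

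Among fibroblast markers LUM rose while COL1A2 and POSTN fell in the combination. A changed share of fibroblasts alone would move them alike. The difference of LUM minus COL1A2, 4.45 ± 0.19, restates the pattern and argues only against a changed share as the sole cause. Its SE takes these genes as independent, though both were measured on the same arrays. A share changed beside other effects stays open, and the markers DCN, COL3A1 and PDGFRB lay below the filter. No biological explanation was tested.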

How the results depend on the processing

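Leaving out IL17A replicate 5 and combination replicate 12 was chosen after seeing the data, and the other alternatives were planned. Of 523 called results for named genes, 437 were called in every setting that tested the gene, apart from changed thresholds and single probe sets. Of 85 called list tests 57 were called in every setting (75 with the preset correlation). With an estimated correlation 60 list tests were called, and 108 by fry. Values below are in the order IL36G, IL17A and the combination against control, the combination against IL36G and against IL17A, IL36G against IL17A, interaction, any group difference, above both singles, above the linear sum, and overlap of the single cytokines. At least 2-fold changes gave 147, 177, 467, 142, 138, 71, 52, 494, 56, 24 and 92, and at least 1.5-fold ones 414, 510, 1070, 410, 386, 226, 123, 1132, 171, 77 and 267. An adjusted p below 0.01 gave 1291 and 1626 for the single cytokines, 1174, 1341, 843 and 95 from the combination against IL36G to the interaction, then 3285, 432, 162 and 705. These follow from stricter limits. Testing all probe sets singly, which tests more features, gave 4161, 4978, 10520, 3857, 4615 and 2862, then 9917, 1236, 462 and 2218 from any group difference on. Array quality weights gave 4242 and 3940 for the combination against IL36G and IL17A, 3303 between the singles and 597 for the interaction. The near-even balance of rises and falls turned with the weights for IL36G (1640 and 1724) and the combination (3040 and 3141) against control, and in several other alternatives. With only the compared groups in the fit, IL17A against control gave 1824 and the combination against IL17A 1471, while IL36G against control gave 2779 and the combination against IL36G 2784. No filter gave an interaction count of 159, and the log2 interaction in place of the linear sum gave 69 above and 47 below. An adjusted p below 0.01 left 48 interactions above the sum and 47 below. The cause of the changes with weights, filter and compared groups was not tested.

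Leaving out each array in turn gave 1566 to 2633 for IL36G, 2182 to 3015 for IL17A and 4187 to 5513 for the combination against control, 1469 to 2742 and 1793 to 2860 for the combination against IL36G and IL17A, 1120 to 2231 between the singles and 130 to 342 for the interaction. It gave 4301 to 5653 for any group difference, 544 to 847 above both singles, 223 to 374 above the linear sum, 946 to 1381 for the overlap and 82 to 89 list tests. Counts moved over 1.5 times without IL36G replicate 7 (1469 and, between the singles, 1142), replicate 9 (1503 and 1190) and replicate 8 (1120), and for the interaction without IL36G replicates 7, 8 and 9 (133, 140 and 130), combination replicates 10 and 12 (136 and 155) and control replicate 3 (149). Without IL17A replicate 5 and combination replicate 12 the interaction count was 238. Dim signal limits small folds: with low values raised to the array median, which sets dim arrays to 1 level, IL36B with IL36G became -0.0212, BCL2A1 with IL17A -0.00926 and CX3CL1 in the combination against IL36G 0.00075.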

Other observations

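The test of the hypothesis below was chosen after the result was seen.

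Of 47 genes of the lists and of the always eligible set that lay below the expression filter, 8 were called between the combination and control without it, 7 higher and 1 lower. TNIP3, an inhibitor of NF-kB signalling that lay above the array median on 0 arrays, had means of 3.97 in control, 4.40 with IL36G, 4.40 with IL17A and 6.46 with the combination, and it was 2.49 higher in the combination than in control without the filter (adjusted p = 1.25e-08). PGLYRP3, a peptidoglycan recognition protein, was 1.01 higher (adjusted p = 5.75e-05), and the receptor IL17RE fell by 0.60 (adjusted p = 0.000188).

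Genes that went in opposite directions with the single cytokines may be lowered by IL17A also when IL36G is present. Of 59 genes higher with IL36G and lower with IL17A, 33 (55.9%) were called lower in the combination than with IL36G alone and 1 higher. Among the other 1104 genes higher with IL36G, 39 (3.53%) were called lower (Fisher's exact test, two-sided, p = 5.26e-28). Of these others, 691 were called higher with IL17A, and the 59 were chosen for falling with it. The choice of genes thus favoured this difference in shares, so the p value cannot decide the question. Genes are not independent replicates, and both comparisons that use the IL36G arrays share their noise. MMP9 was -3.06, IL2RG -1.93 and GATA6 -1.22 in the combination against IL36G; GATA6 was chosen after their values were seen. The hypothesis was found and tested on the same arrays.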
